A study of Mus musculus with 16 samples.

How the data were processed

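Total RNA from eWAT and liver of wild-type and Fgf1 null mice was hybridized by the authors to Illumina MouseRef-8 bead arrays, 1 colour, with 25697 probes each. Processing by the submitters was in GenomeStudio, whose version is not given. The deposited table of non-normalized values holds, for each of the 16 arrays, the intensity of every probe on a linear scale and a detection p-value, the chance of such brightness under the array's negative controls. A further deposited table holds normalized intensity, also linear, whose method the authors do not state; its columns share their quartiles, with medians near 134.7. Each array's column in that table was checked against the non-normalized values and had a rank correlation of 1 with its own array and at most 0.955 with any other. The arrays are at the age of 24 weeks and 16 weeks of diet in the labels, and no slide or scan date is given. Probe annotation came from the platform table of 2016, in which 23978 probes carry 1 gene symbol and 1719 carry none. Of the named probes 23962 matched the RefSeq gene table of assembly GRCm38.p6 by Entrez identifier, and 0 symbols changed. The files name no genome build, so no coordinates are given and genes go by symbol.

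Values were taken from the non-normalized table. In R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table, the neqc method estimated the background of each array from the detection p-values, added an offset of 16, and quantile normalized the 8 arrays of a tissue on the log2 scale; tissues were handled apart because most genes differ between them. Background correction with a small offset spreads out dim probes, so differences of dim genes are larger than in uncorrected values. Near the top of the scale the scanner limits the signal: 1 to 14 probes per array were above 60000, and differences of such probes are compressed. A probe was kept when its detection p was under 0.05 on both arrays of at least 1 group of the tissue, which left 15839 probes in eWAT and 11580 in liver. The brightest kept probe stood for its gene, giving 10995 genes and 940 unnamed probes in eWAT and 8211 genes and 683 unnamed probes in liver. The number of arrays limits the precision, with a median SD between arrays of a group of 0.153 in eWAT and 0.159 in liver on the log2 scale.

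Groups were taken from the labels. For each tissue, limma fitted the 8 arrays with a mean per group, 4 residual degrees of freedom and an empirical Bayes prior of 3.75 (eWAT) or 3.64 (liver) degrees of freedom. The contrasts were HFD minus chow in each genotype, Fgf1 null minus wild-type on each diet, and the difference of the 2 diet contrasts. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast and a change of at least 2-fold. A separate fit averaged the 2 arrays of each RNA sample and used an additive model of diet and genotype on the 4 samples of a tissue, with 1 residual degree of freedom. For a gene whose probe was detected on no array of the lower group, the fold is given as at least a bound: the mean of the higher group against the lowest detected signal of each array of the lower group. Where the probe was detected on 1 of 2 arrays the fitted difference is given, which rests on a level near background. Both fits were tested on simulated data. The array fit recovered 100% of 4-fold changes in eWAT and 99% in liver with 0 false calls in each for genotype on HFD. Its gene spreads were the moderated variances of that same fit, with no variation between RNA samples, so the 0 false calls say little. The simulation of the fit to RNA samples first used the moderated variances of that fit as gene spreads, and after its false calls were seen the spreads were drawn from the fitted prior. In liver the first form gave 57 false calls beside 200 changed genes and the second 14, and in eWAT both recovered 0% of the changes. Each form is 1 random draw, and other draws differ.

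Gene lists for 37 pathways and cell types, including organs that lie next to the tissues, were fixed before the data were examined, as were the comparisons, the alternatives and the rule for naming genes. For each list the text gives the members called in each direction among those measured, the median log2 difference, and the percentile of that median among 10000 random lists of the same size drawn from 20 bins of mean intensity. With 1 RNA sample per group the percentile describes the samples and tests no condition. Counts adjusted over the list alone equalled those over all genes tested for every list and comparison. Medians are also given with undetected genes at their bound where this moved a printed median by at least 0.1 in a comparison of 2 groups; this was not computed for the interactions, whose medians hold such genes at their fitted values. Named genes are, per comparison, the 5 largest called increases and decreases with arrays of the 2 groups not overlapping, up to 4 of the largest called members of each list, and some genes chosen in advance that are given whether called or not. The text takes the largest first and may name fewer. Size was ranked by the fitted difference, so the rank of a gene given as a bound is not measured.

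The analysis was repeated with normalization over all 16 arrays, quantile normalization without background correction, median scaling in place of quantiles, the authors' normalized values, a detection p under 0.01 or no filter, a 1.5-fold minimum, the mean of a gene's probes, the replicate number as a block, an intensity trend with robust variances, both tissues in the same fit, and each array left out in turn. Each changed 1 choice except the fit of both tissues, which changes normalization and the genes tested with it, and the authors' values, whose processing is not stated. Added after seeing the data were a count without genes that follow markers of other organs, meaning list members and genes correlating over 0.95 across the 8 eWAT arrays with the mean of the hepatocyte, exocrine pancreas, sperm or epididymis genes (1465 in all), and list medians without members at least 4-fold higher in wild-type HFD liver than in the chow eWAT labelled Fgf1 null. The count is not read, since its filter picks genes by their pattern over the samples compared. The medians are read only for comparisons without the chow eWAT labelled Fgf1 null, whose levels choose the members. Figures were drawn with Python 3.11.15. A slide effect was not fitted, since the files give no slide. With 1 RNA sample per group, the spread within a group could not be estimated.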

Results

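Gene expression was measured in epididymal white adipose tissue (eWAT), the fat depot attached to the epididymis, and in liver. The mice were wild-type or Fgf1 null, the latter lacking the gene for fibroblast growth factor 1, a secreted growth factor. They were 24 weeks old and had been fed normal chow or a high-fat diet (HFD) for 16 weeks. The tissues, genotypes and diets make 8 groups, each measured on 2 arrays that the labels call technical replicates, so each group is represented by 1 RNA sample and the series holds 16 arrays. The labels do not say whether an RNA sample came from a single mouse or a pool. Per array, 13570 to 15399 of the 25697 probes were detected in eWAT and 10626 to 11650 in liver, at median raw intensities of 128 to 161 and 103 to 115. The 2 arrays of a group correlated across probes at r = 0.991 to 0.995 in eWAT and 0.988 to 0.994 in liver. Differences are log2 values ± the standard error from limma, with n = 2 arrays in each group, and a gene is called higher or lower at an adjusted p under 0.05 and a change of at least 2-fold. The standard error is that of arrays of the same RNA, so every such call compares RNA samples and says nothing of the spread between mice.

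Fgf1 itself was read first, as a check of the genotype labels. In liver its level was 10.31 ± 0.11 (log2 intensity, SD, n = 2) in wild-type chow, 9.66 ± 0.04 in wild-type HFD, 9.36 ± 0.17 in Fgf1 null chow and 8.23 ± 0.07 in Fgf1 null HFD. Fgf1 was thus lower in both null livers, by -0.95 ± 0.13 on chow (adjusted p 0.0091, under 2-fold and not called) and by -1.43 ± 0.13 on HFD. In eWAT the level was 9.32 ± 0.22 in wild-type chow, 10.78 ± 0.11 in wild-type HFD, 9.99 ± 0.27 in Fgf1 null chow and 9.28 ± 0.13 in Fgf1 null HFD. Fgf1 in the chow eWAT sample labelled Fgf1 null was thus 0.67 ± 0.17 above wild-type (adjusted p 0.012, under 2-fold and not called), while on HFD it was called lower by -1.50 ± 0.17. The position of the probe relative to the deleted part of the gene is not given, and a probe outside that part does not report the deletion. With the mean of the gene's probes, which include a second, dimmer probe, the HFD calls in both tissues were lost, at -0.63 in eWAT and -0.84 in liver. Camk2b, a subunit of a calcium-dependent protein kinase, separated the genotype labels in every pair: it was at least 9.17-fold higher in Fgf1 null liver on chow and at least 13.0-fold on HFD, not being detected in wild-type liver, and higher in eWAT labelled Fgf1 null by 3.28 ± 0.21 and 2.57 ± 0.21. In eWAT Camk2b is outside the rule for named genes and was chosen after its values were seen.

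The diet comparison in wild-type eWAT asks how fat labelled wild-type differs between HFD and chow. Wild-type eWAT on HFD had more transcripts of fat storage, macrophages and matrix than on chow. Lep, which encodes the fat cell hormone leptin, was higher by 2.81 ± 0.13, and Pparg, the nuclear receptor that drives fat cell differentiation, by 2.04 ± 0.11. Adgre1, a macrophage surface receptor, was higher by 2.56 ± 0.14, and the collagen gene Col1a1 by 1.73 ± 0.16. Fgf1 rose with them, by 1.46 ± 0.17, while Adipoq, which encodes adiponectin, differed by 0.46 ± 0.13 and was not called.

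Of 26 measured adipocyte and PPARγ target genes 17 were higher and 0 lower on HFD in wild-type eWAT, with a median of 1.41, at percentile 100 of random lists of matched intensity. Among them Fabp5, a fatty acid carrier, rose by 3.80 ± 0.27, Dgat2, which makes triglyceride, by 3.47 ± 0.15, and Agpat2, an enzyme of phosphatidic acid synthesis, by 3.18 ± 0.15. Of 35 macrophage genes 29 were higher and 1 lower (median 1.77, percentile 100), with Arg1 at 6.68 ± 0.16, Mmp12 at 3.67 ± 0.12, Vsig4 at 3.18 ± 0.13 and Trem2 at 3.16 ± 0.16; Arg1 is also abundant in liver and Vsig4 in its resident macrophages. Extracellular matrix genes went the same way, 20 of 34 higher and 1 lower (median 1.32, and 1.16 with undetected genes at their bound; percentile 100), led by the collagens Col15a1 (3.54 ± 0.17) and Col5a3 (at least 7.61-fold, not detected on chow). Inflammatory cytokine and chemokine genes were higher in 14 of 24 and lower in 0 (median 1.21, percentile 100), among them Ccl7 at 2.83 ± 0.17 and Ccl11 at 2.69 ± 0.13. Among 15 genes of FGF ligands and receptors 6 were higher and 1 lower (median 0.70, percentile 98.7), the largest rise being that of Fgf13 at 4.65 ± 0.17. Fabp5 was detected on 1 of 2 chow arrays.

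Transcripts of other organs differed alongside these groups in wild-type eWAT. Of 14 hepatocyte genes 13 were higher on HFD and 0 lower (median 5.79, percentile 100), such as Ttr at 7.08 ± 0.17, Serpina1d at 6.73 ± 0.14 and Ambp at 6.70 ± 0.15, which encode plasma proteins. The exocrine pancreas was represented by 5 lipase genes, all higher (median 6.78, and 6.39 at the bound), and by 32 other acinar genes, 27 higher and 1 lower (median 5.12, and 4.93 at the bound), both at percentile 100. The largest increases in this comparison were in that group: the elastase Cela2a at 8.91 ± 0.15, the pancreatic colipase Clps at 8.24 ± 0.16, the amylase Amy2a5 at 7.94 ± 0.13, Try4 at least 178-fold and Zg16 at least 181-fold. Cel, the bile salt dependent lipase, was at least 83.8-fold higher, and Pnlip, pancreatic lipase, is not among the genes tested. The lipase list was drawn up with knowledge of the study, so its direction is not independent evidence. Genes of epididymis, testis and seminal vesicle were lower in 16 of 21 and higher in 0 (median -5.14, percentile 0). Npy and the epididymal genes Wfdc13, Defb42, Ly6f and Defb22 had the largest falls, Wfdc13 being at least 527-fold and Defb42 at least 431-fold lower, Npy at -9.09 ± 0.19, Ly6f at -8.72 ± 0.23 and Defb22 at -8.68 ± 0.14. Clps and Amy2a5 were detected on 1 of 2 chow arrays, and Npy and Ly6f on 1 of 2 HFD arrays.

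Metabolic groups that liver also expresses moved with the hepatocyte genes in wild-type eWAT. Acute phase genes were higher in 15 of 19 and lower in 1 (median 3.85, percentile 100), with Hamp2 at least 130-fold and Hpx at 7.31 ± 0.16 higher. Genes of de novo lipogenesis, the synthesis of fatty acids, were higher in 10 of 19 and lower in 1 (median 1.13, and 0.90 at the bound; percentile 100), with Thrsp at 4.06 ± 0.14 and Acss2 at 3.10 ± 0.11. Genes of cholesterol biosynthesis were higher in 7 of 16 (median 0.80, percentile 98.9), and those of fatty acid oxidation higher in 12 of 27 and lower in 2 (median 0.93, percentile 100). Without members at least 4-fold higher in liver, a restriction chosen after seeing the data, the medians were 1.54 for 7 acute phase genes, 0.63 for 9 lipogenic genes, 0.78 for 21 fatty acid oxidation genes, 1.45 for 4 cholesterol biosynthesis genes, 1.59 for 25 adipocyte genes and 1.72 for 33 macrophage genes.

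Altogether limma called 3969 of 11935 genes and unnamed probes in wild-type eWAT between HFD and chow, 1978 higher and 1991 lower (largest adjusted p among them 0.0428). Of the called genes with several probes, 3 of 890 had another probe called the other way. Quantile normalization without background correction called 2305 genes, the authors' normalized values called 2338, and a minimum of 1.5-fold called 6131. Scaling arrays to a common median in place of quantiles gave 2453 higher and 1823 lower, with the median of all genes at 0.30. Because each group is 1 RNA sample, leaving out either sample ends the comparison.

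**Figure D1:**
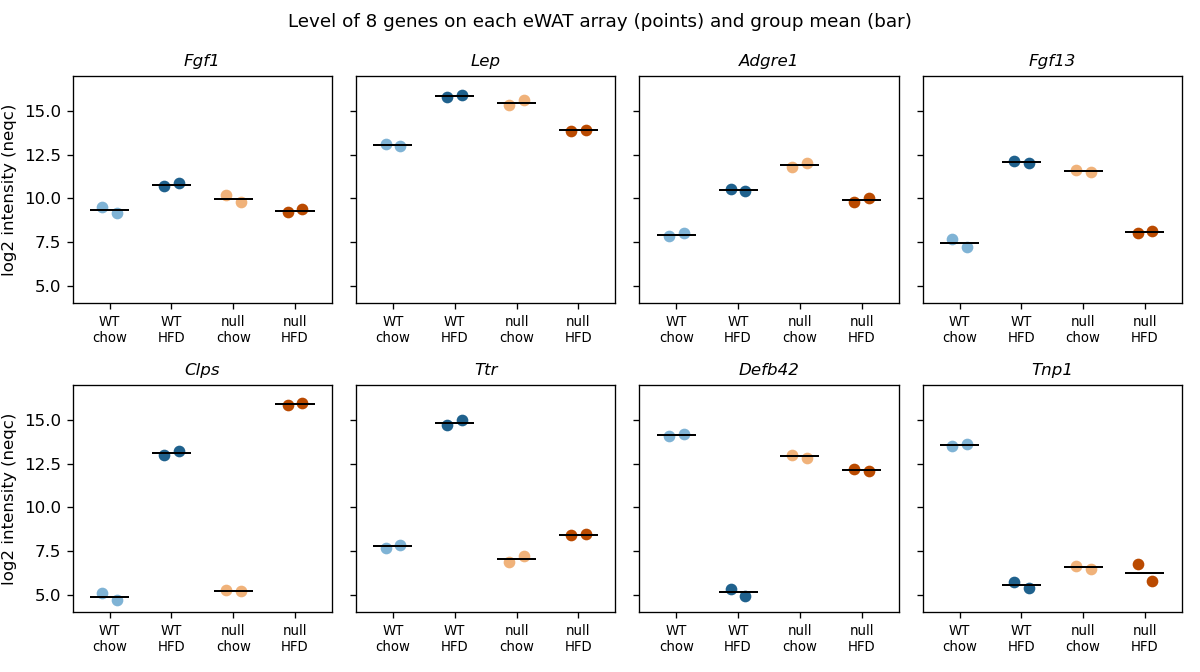
Level of 8 genes in eWAT, in log2 intensity on the vertical axis, for the 4 groups on the horizontal axis; points are single arrays and bars the mean of 2 arrays. Fgf1 sits at 9.32 in wild-type chow and 9.99 in the chow sample labelled Fgf1 null, Lep runs from 13.04 in wild-type chow to 15.85 in wild-type HFD, and Clps was 4.88 and 5.23 on chow against 13.12 and 15.91 on HFD.

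The same diet comparison in eWAT labelled Fgf1 null ran the other way for leptin, macrophage and matrix genes. Lep fell by 1.58 ± 0.13 on HFD, Adgre1 fell by 2.00 ± 0.14 and Col1a1 fell by 1.28 ± 0.16. Fgf13 fell by 3.49 ± 0.17, where it had risen in wild-type. Pparg differed by 0.83 ± 0.11 and Adipoq by 0.35 ± 0.13, and Fgf1 by -0.71 ± 0.17, none of them called.

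Macrophage genes were lower on HFD in 23 of 35 and higher in 1 in eWAT labelled Fgf1 null (median -1.61, and -1.49 with undetected genes at their bound; percentile 0), led by Mmp12 at -3.91 ± 0.12, Trem2 at -3.80 ± 0.16 and Gpnmb at -2.92 ± 0.13. Inflammatory cytokine and chemokine genes were lower in 10 of 24 and higher in 2 (median -0.88, percentile 0), with Ccl3 at least 4.93-fold lower and Ccl7 at -2.77 ± 0.17. Extracellular matrix genes were lower in 13 of 34 and higher in 3 (median -0.70, and -0.59 at the bound; percentile 0), Col15a1 among them at -2.18 ± 0.17. Adipocyte genes split, 4 of 26 higher and 5 lower (median 0.22, percentile 99.5): Pck1, an enzyme of glycerol synthesis in fat, rose by 2.82 ± 0.16, whereas Cidea, detected on 1 of 2 HFD arrays, fell by 2.42 ± 0.20 and Dgat2 fell by 2.06 ± 0.15. Fatty acid oxidation genes were higher in 7 of 27 and lower in 0 (median 0.44, percentile 100), among them Acot4 at 2.53 ± 0.14 and the hormone gene Fgf21 at 2.37 ± 0.22. Cholesterol biosynthesis genes were lower in 4 of 16 and higher in 0 (median -0.76, percentile 0), with Lss at -1.37 ± 0.12, which fell under 2-fold without background correction, at -0.85. De novo lipogenesis genes showed no common direction, 2 of 19 higher and 2 lower (median -0.32, percentile 1.7).

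The exocrine pancreas genes were again the largest increases in the HFD sample labelled Fgf1 null, beside all of these groups. All 5 lipase genes were higher (median 9.94, and 9.55 at the bound), as were 29 of 32 other acinar genes with 0 lower (median 9.01, and 8.63 at the bound), both at percentile 100. The trypsin gene Try4 was at least 1653-fold higher, Try10 at least 1582-fold, Try5 at least 1265-fold, Zg16 at least 1355-fold and Cel at least 750-fold, while Clps rose by 10.69 ± 0.16, a compressed difference since both HFD arrays were near the top of the scale. Ins2, an insulin gene of pancreatic islets, was at least 6.12-fold higher. Hepatocyte genes were higher in 5 of 14 and lower in 2 (median 0.28, percentile 97.9), with Cyp2e1 at 3.95 ± 0.12 and Serpina1b at -3.19 ± 0.12, and genes of epididymis and testis were lower in 4 of 21 (median -0.41, percentile 0.34). The largest decreases were in Tph2, a serotonin synthesis enzyme, at -6.79 ± 0.19, and in Rgs1 at -4.82 ± 0.21, Lipf at -4.45 ± 0.23, Atf3 at -4.40 ± 0.16 and Hal at -4.32 ± 0.12. Tph2 was detected on 1 of 2 HFD arrays, and Cyp2e1 was near the top of the scale on 1 of them.

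For diet in eWAT labelled Fgf1 null, limma called 1217 genes, 499 higher and 718 lower (largest adjusted p 0.0492), and none of the 252 with several probes had another called the other way. Without background correction the count was 583, with the authors' values 576, and with a 1.5-fold minimum 2863. Median scaling gave 382 higher and 907 lower, with the median of all genes at -0.12.

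On chow, the genotype comparison in eWAT asks what differs without the diet. The chow eWAT sample labelled Fgf1 null had higher macrophage, matrix and fat storage transcripts than wild-type chow. Lep was higher by 2.43 ± 0.13, Col1a1 by 2.17 ± 0.16 and Pparg by 1.16 ± 0.11, and Adgre1 stood at 11.90 ± 0.13 (SD) against 7.91 ± 0.11. Adipoq differed by 0.41 ± 0.13 and was not called. The largest increases were in Tph2 (6.62 ± 0.19), Mmp12, a macrophage elastase (6.50 ± 0.12), Rgs1 (6.24 ± 0.21), Saa3, a serum amyloid made in fat (5.48 ± 0.18), and Trem2, a lipid receptor of macrophages (5.33 ± 0.16).

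Macrophage genes were higher in 31 of 35 and lower in 1 between the chow eWAT samples (median 2.61, percentile 100), Cd84 at 4.58 ± 0.12 and Gpnmb at 4.31 ± 0.13 among them. Extracellular matrix genes were higher in 24 of 34 and lower in 0 (median 1.65, percentile 100), with the protease Mmp3 at 3.92 ± 0.18, Col15a1 at 3.28 ± 0.17 and Col3a1 at 3.01 ± 0.13. Cytokine and chemokine genes were higher in 17 of 24 and lower in 0, with Ccl7 at 3.86 ± 0.17 and Ccl9 at 3.74 ± 0.13. Adipocyte genes were higher in 16 of 26 and lower in 0 (median 1.23, percentile 100), with Fabp5 at 3.20 ± 0.27 and Dgat2 at 3.13 ± 0.15. Genes of FGF ligands and receptors were higher in 5 of 15 and lower in 2 (median 0.67, percentile 99.1), Fgf13 at 4.11 ± 0.17. Acute phase genes were higher in 6 of 19 and lower in 1 (median -0.024, percentile 29.7), de novo lipogenesis genes higher in 5 of 19 and lower in 1 (median 0.11, percentile 62.9), cholesterol biosynthesis genes higher in 6 of 16 (median 0.42, percentile 89.8) and fatty acid oxidation genes higher in 4 of 27 and lower in 3 (median 0.33, percentile 89.9). Mmp3 and Fabp5 were detected on 1 of 2 wild-type arrays.

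Beside these groups, sperm and testis transcripts were abundant in the wild-type chow eWAT sample and lower in the one labelled Fgf1 null. Tnp1 was at 13.49 and 13.60 on the wild-type chow arrays and at most 6.73 on the other eWAT arrays. Genes of epididymis, testis and seminal vesicle were lower in 9 of 21 and higher in 1 (median -0.73, percentile 0.03), with the protamine Prm1, which packs sperm DNA, at -5.82 ± 0.12 and the transition protein gene Tnp1 at -6.98 ± 0.28. The largest falls were of the same kind: Hils1 was at least 156-fold and Cypt3 at least 129-fold lower, Fabp9 fell by 7.25 ± 0.15, H2al1e fell by 7.22 ± 0.20 and Spata19 fell by 7.21 ± 0.11. Hepatocyte genes were higher in 2 of 14 and lower in 3 (median -0.37, percentile 2.16), with Serpina1d at 3.85 ± 0.14 and Cyp2e1 at -3.27 ± 0.12. None of the pancreatic lipase genes was called (median 0.0070), Cel being detected in neither sample and Clps, detected on 1 of 2 wild-type arrays, at 0.35 ± 0.16, nor did the other acinar genes move together (2 higher and 2 lower of 32, median -0.037).

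Between the chow eWAT samples limma called 3263 genes, 1641 higher and 1622 lower (largest adjusted p 0.0438), with another probe called the other way in 4 of 714. Without background correction 1834 genes were called, with the authors' values 1850 and with a 1.5-fold minimum 5449. Median scaling gave 2137 higher and 1410 lower, with the median of all genes at 0.27, so the even split rests on the quantile step.

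On HFD, the genotype comparison in eWAT asks how fat labelled Fgf1 null differs once both genotypes eat the diet. The sample labelled Fgf1 null had more pancreatic and epididymal transcripts and fewer hepatocyte, lipogenic and cholesterol synthesis transcripts than wild-type HFD. Lep fell by 1.96 ± 0.13 between them and Fgf13 fell by 4.02 ± 0.17, while Fgf21 rose by 1.51 ± 0.22. Adgre1 differed by -0.57 ± 0.14, Col1a1 by -0.85 ± 0.16, Adipoq by 0.30 ± 0.13 and Pparg by -0.055 ± 0.11, none of them called.

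All 5 pancreatic lipase genes were higher in the HFD eWAT sample labelled Fgf1 null (median 3.30, percentile 100): Pla2g1b by 4.26 ± 0.13, Pnliprp2 by 3.97 ± 0.11, Cel by 3.30 ± 0.12 and Clps by 2.79 ± 0.16, compressed because Clps was near the top of the scale on both arrays of that sample. Of the other acinar genes 29 of 32 were higher and 2 lower (median 3.32, percentile 100), with Reg2 at 6.25 ± 0.13, Reg3b at least 38.1-fold and Prss3 at 5.05 ± 0.12, and Ins2 was at least 5.36-fold higher. Genes of epididymis, testis and seminal vesicle were higher in 12 of 21 and lower in 0 (median 2.66, and 2.04 at the bound; percentile 100). The largest increases included epididymal genes, Wfdc13 at least 146-fold, Serpina1f at least 104-fold, Defb42 at least 108-fold and Spink8 at 7.35 ± 0.11. Npy was also among them, at 7.29 ± 0.19. Hepatocyte genes were lower in 12 of 14 and higher in 0 (median -5.56, and -5.23 at the bound; percentile 0), with Ttr at -6.42 ± 0.17 and Apoa2 at -6.32 ± 0.13. The largest decreases were liver transcripts too: Ces1c at least 122-fold, Cyp2c70 at least 70.8-fold, Hpx at -6.62 ± 0.16 and Hamp, which encodes the iron hormone hepcidin, at -6.54 ± 0.16. Npy was detected on 1 of 2 wild-type arrays and Hamp on 1 of 2 arrays labelled Fgf1 null.

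De novo lipogenesis genes were lower in 10 of 19 and higher in 0 between the HFD eWAT samples (median -1.23, and -0.94 at the bound; percentile 0), with Acss2 at -2.87 ± 0.11 and Thrsp at -2.76 ± 0.14. Cholesterol biosynthesis genes were lower in 9 of 16 and higher in 0 (median -1.11, percentile 0), Lss at -1.75 ± 0.12, and acute phase genes lower in 12 of 19 and higher in 1 (median -2.26, percentile 0). Without the members at least 4-fold higher in liver, the medians were -1.24 for 9 lipogenic, -1.07 for 4 cholesterol synthesis, -0.0013 for 7 acute phase, -0.081 for 21 fatty acid oxidation, -0.12 for 25 adipocyte and -0.21 for 33 macrophage genes. Adipocyte genes were lower in 7 of 26 and higher in 1 (median -0.090, percentile 23.6), with Agpat2 at -2.42 ± 0.15 and Dgat2 at -2.40 ± 0.15. Macrophage genes were lower in 8 of 35 and higher in 1 (median -0.27, percentile 0.06), led by Arg1 at -5.55 ± 0.16 and Clec4f, a marker of liver macrophages, at least 5.21-fold, with Trem2 at -1.64 ± 0.16. Matrix genes were lower in 8 of 34 and higher in 2 (median -0.22, percentile 1.02), Col15a1 at -2.45 ± 0.17, and cytokine genes lower in 5 of 24 and higher in 1 (median -0.23, percentile 1.23). Fatty acid oxidation genes went both ways, 3 of 27 higher and 4 lower (median -0.18, percentile 3.6), with Pdk4 at 2.19 ± 0.11 and Cyp4a14 at -3.64 ± 0.16.

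On HFD limma called 1346 genes between the eWAT samples, 629 higher and 717 lower (largest adjusted p 0.0487), and none of 284 with several probes had another called the other way. Without background correction 695 genes were called, with the authors' values also 695, and with a 1.5-fold minimum 2818. Median scaling gave 524 higher and 819 lower.

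The interaction in eWAT, the diet difference in samples labelled Fgf1 null minus that in wild-type, tests whether the diet differences themselves differ. Macrophage genes had a lower diet difference in eWAT labelled Fgf1 null in 32 of 35 and a higher one in 1 (median -3.30, percentile 0), matrix genes in 23 of 34 against 2 (median -2.01, percentile 0) and adipocyte genes in 14 of 26 against 2 (median -1.10, percentile 0). Hepatocyte genes had a lower difference in 12 of 14 and a higher one in 1 (median -5.29, percentile 0). Epididymis and testis genes had a higher difference in 16 of 21 (median 4.60, percentile 100), and the other acinar genes in 29 of 32 against 2 (median 3.51, percentile 100). In all 4713 genes were called, 2299 with a higher and 2414 with a lower diet difference (largest adjusted p 0.0495), and 10 of 1020 had another probe called the other way. Quantile values without background correction called 2947 genes, the authors' values 2987, and median scaling gave 1960 higher and 3290 lower.

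Across all genes, the diet differences of wild-type eWAT and of eWAT labelled Fgf1 null correlated at r = 0.10 (Spearman's rho -0.049), a correlation across genes, which are not independent replicates. Genes called higher in wild-type and lower in the other genotype numbered 343, against 119 expected by chance from the counts, and those called higher in both numbered 165 against 82.7. The reverse, lower in wild-type and higher in the other genotype, numbered 48 against 83.2, and those lower in both 111 against 120, so the excess lay among genes higher in wild-type. The 2 genotype differences, on chow and on HFD, correlated at r = -0.18 (rho -0.28), with 263 genes higher on chow and lower on HFD against 98.6 expected and 218 the other way against 85.5.

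**Figure D2:**
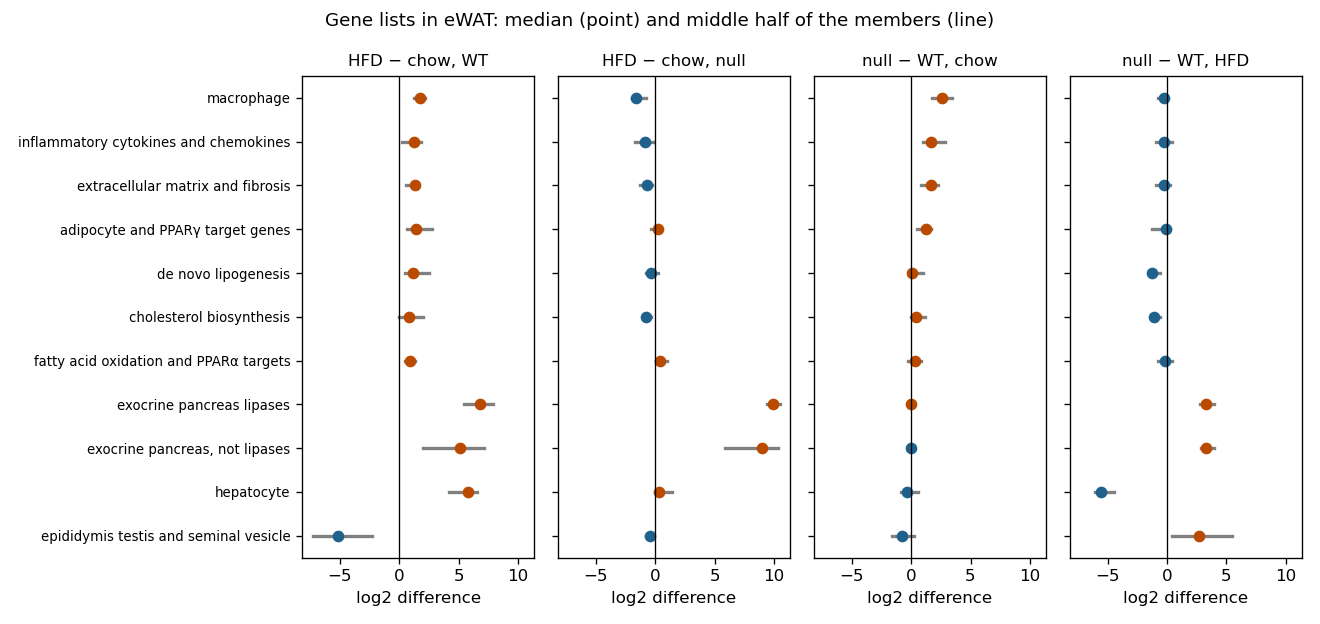
Gene lists in eWAT, each with the median log2 difference of its members as a point and the central quartiles of the members as a line, for 4 comparisons side by side. Macrophage genes lie at 1.77 for diet in wild-type and -1.61 for diet in Fgf1 null, and hepatocyte genes at 5.79 for diet in wild-type and -5.56 for genotype on HFD.

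In wild-type liver, where the diet comparison asks the same question, HFD went with higher fatty acid and cholesterol synthesis transcripts and lower fatty acid oxidation transcripts than chow. Thrsp, a regulator of fatty acid synthesis, rose by 5.23 ± 0.15, and Srebf1, the transcription factor that drives that pathway, by 3.90 ± 0.13. Cyp4a14, a fatty acid hydroxylase under PPARα, fell by 7.89 ± 0.18 and Cyp4a31 of the same family fell by 7.61 ± 0.13. Cidec, which encodes a lipid droplet protein and was detected on 1 of 2 HFD arrays, fell by 3.58 ± 0.28 and the hormone gene Fgf21 fell by 1.59 ± 0.15. Scd1, a fatty acid desaturase, rose by 1.25 ± 0.13, which fell under 2-fold with the authors' values (0.98), while Fgf1 at -0.65 ± 0.13 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at -0.52 ± 0.12 were not called.

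Genes of de novo lipogenesis were higher in 14 of 18 and lower in 1 on HFD in wild-type liver (median 1.55, and 1.36 at the bound; percentile 100), Acss2 at 2.40 ± 0.13 among them and the elongase Elovl6 at 10.56 ± 0.30 (SD) against 8.05 ± 0.17. Cholesterol biosynthesis genes were higher in 12 of 17 and lower in 0 (median 1.49, percentile 100), with Fdps at 13.86 ± 0.20 (SD) against 10.87 ± 0.03, and Nsdhl higher by 2.60 ± 0.30 and Pmvk by 2.55 ± 0.15. Fatty acid oxidation genes were lower in 17 of 27 and higher in 0 (median -1.17, percentile 0), with Acot3 at -5.63 ± 0.12 and Acot1 at -4.77 ± 0.26. Lipid droplet genes were lower in 6 of 16 and higher in 0 (median -0.65, percentile 0), led by Cidec and by Plin4 at -3.27 ± 0.14. Acute phase genes were higher in 9 of 21 and lower in 1 (median 0.69, percentile 100), with Hamp2 at 4.59 ± 0.13, Saa2 at 3.88 ± 0.16 and Lcn2 at 3.54 ± 0.13. Macrophage genes were higher in 6 of 28 and lower in 0 (median 0.54, percentile 100). Xenobiotic metabolism genes were lower in 5 of 21 and higher in 1 (median -0.21, percentile 1.82), Cyp3a11 at -4.47 ± 0.13 and Cyp2b10 at -3.24 ± 0.14. Clock genes were higher in 4 of 15 and lower in 2 (median 0.35, percentile 99.8), with Dbp at 1.98 ± 0.13. Clock genes with the phase of Dbp minus those with the phase of Arntl differed by 1.91. Diet was thus not separated from time of day at collection in wild-type liver. Outside these lists, the largest increases included Serpina7, a carrier of thyroid hormone, at 4.85 ± 0.31, Xlr4a at 4.74 ± 0.13 and Chrna4, at least 12.9-fold, and the decreases Gm4952 at -4.71 ± 0.22. Serpina7 was detected on 1 of 2 chow arrays and Cyp2b10 on 1 of 2 HFD arrays.

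Between HFD and chow in wild-type liver limma called 509 of 8894, 288 higher and 221 lower (largest adjusted p 0.0495), and 1 of 99 had another probe called the other way. Without background correction 227 were called, with the authors' values 238 and with a 1.5-fold minimum 1389. Median scaling gave 595 higher and 121 lower, with the median of all genes moved to 0.26.

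**Figure D3:**
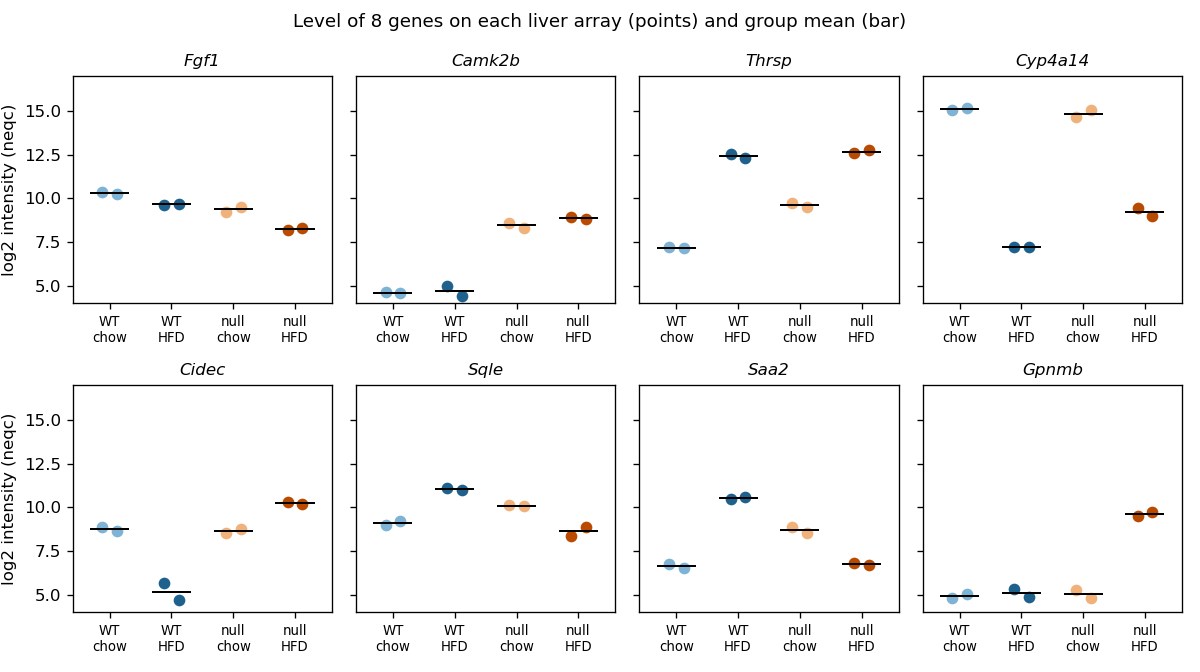
Level of 8 genes in liver, in log2 intensity on the vertical axis, for the 4 groups on the horizontal axis; points are single arrays and bars the mean of 2 arrays. Camk2b is near 4.59 and 4.70 in wild-type liver and at 8.45 and 8.86 in Fgf1 null liver, Cidec ranges from 5.18 in wild-type HFD to 10.25 in Fgf1 null HFD, and Gpnmb reaches 9.60 in Fgf1 null HFD.

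Fgf1 null liver on HFD had higher lipid droplet, macrophage and fatty acid synthesis transcripts than on chow. Cidea, another lipid droplet protein, was at least 33.2-fold higher, and Cidec rose by 1.61 ± 0.28, where it had fallen in wild-type. Fgf21 rose by 1.73 ± 0.15 and Scd1 by 1.48 ± 0.13. Gpnmb, a glycoprotein of lipid-laden macrophages, rose by 4.56 ± 0.22, its probe being detected on 1 of 2 chow arrays. Fgf1 fell by 1.13 ± 0.13, a change under 2-fold without background correction (-0.92), and Cyp7a1 at -0.97 ± 0.12 was not called.

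Of 28 macrophage genes 20 were higher and 1 lower on HFD in Fgf1 null liver (median 1.63, percentile 100), with Trem2, detected on 1 of 2 chow arrays, at 2.78 ± 0.22 and Tyrobp at least 4.76-fold higher, and the resident macrophage gene Cd163 at least 6.51-fold lower. Neutrophil and mast cell genes were higher in 6 of 10 (median 1.19, and 0.67 at the bound; percentile 100), S100a9 at 2.77 ± 0.15 and S100a8 at 2.74 ± 0.18 among them. Cytokine and chemokine genes were higher in 8 of 20 and lower in 2 (median 0.81, and 0.61 at the bound; percentile 100), with Ccl4 at least 7.89-fold and Ccl5 at 2.55 ± 0.14. Extracellular matrix genes were higher in 7 of 27 and lower in 0 (median 0.88, and 0.64 at the bound; percentile 100), and cell cycle genes higher in 7 of 16 and lower in 0 (median 0.92, and 0.65 at the bound; percentile 100), with Mcm5 at 2.13 ± 0.19 and Ccnd1 at 2.07 ± 0.13. Lipid droplet genes were higher in 7 of 16 and lower in 2 (median 0.57, percentile 100), with the triglyceride enzyme gene Mogat1 at 2.59 ± 0.15 and the lipase Lpl at 2.45 ± 0.13.

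De novo lipogenesis genes were higher in 9 of 18 and lower in 1 in Fgf1 null liver on HFD (median 0.95, percentile 100), Thrsp at 3.04 ± 0.15 and Acaca at 2.23 ± 0.17. Fatty acid oxidation genes were lower in 6 of 27 and higher in 1 (median -0.55, percentile 0), Cyp4a31 at -5.65 ± 0.13 and Cyp4a14 at -5.62 ± 0.18. Cholesterol biosynthesis genes were lower in 5 of 17 and higher in 0 (median -0.47, percentile 0.03), with Msmo1 at -1.78 ± 0.13 and Sqle, the squalene epoxidase, at -1.45 ± 0.18. Acute phase genes went both ways, 4 of 21 higher and 4 lower (median 0.16, percentile 92.3), with the metallothionein Mt1 at -3.77 ± 0.11. Genes of gluconeogenesis and insulin response were lower in 4 of 12 (median -0.38, percentile 0.41), Igfbp2 at -3.24 ± 0.12 and Pck1 at -2.06 ± 0.19. Cyp2b9, a cytochrome more abundant in female liver, was at least 21.7-fold higher. Serpina7 at 5.81 ± 0.31, detected on 1 of 2 chow arrays, and Nrep at 3.96 ± 0.12 completed the largest increases, and Moxd1, at least 14.2-fold lower, and Etnppl, at -3.44 ± 0.25, were among the largest falls.

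For diet in Fgf1 null liver limma called 763 genes, 523 higher and 240 lower (largest adjusted p 0.0420), and none of 148 had another probe called the other way. Without background correction 310 were called, with the authors' values 369 and with a 1.5-fold minimum 1773. Median scaling gave 715 higher and 170 lower, with the median of all genes at 0.18.

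On chow, Fgf1 null and wild-type liver differed in few genes. The largest fitted increases were of Camk2b, at least 9.17-fold, Sugct, at least 5.92-fold, and Cabyr, at least 5.98-fold. With them were the chemokine Cxcl1 at 3.06 ± 0.13 and Fbf1 at 3.03 ± 0.12. The order among these genes is not measured, since a bound has no exact size. Cyp7a1 fell by 1.32 ± 0.12, and Fgf21 at -0.86 ± 0.15, Scd1 at 0.12 ± 0.13 and Cidec at -0.12 ± 0.28 were not called. The largest fitted falls included Serinc2 (at least 3.59-fold), Wfdc12 (at least 3.51-fold), Rhox5 (at least 2.49-fold) and Acnat2 (-1.83 ± 0.19). The first 3 of these are bounds, so their rank is not measured. They fell under 2-fold without background correction, at -0.91, -0.89 and -0.74.

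Acute phase genes were higher in 6 of 21 and lower in 0 in Fgf1 null liver on chow (median 0.63, percentile 100), with Mt2 at 2.39 ± 0.20, Saa2 at 2.08 ± 0.16 and Lcn2 at 1.72 ± 0.13. Clock genes were higher in 3 of 15 and lower in 2 (median 0.52, percentile 100), Nr1d1 among them at -1.56 ± 0.12. Genes that depend on sex and growth hormone were lower in 4 of 18 and higher in 0 (median -0.14, percentile 3.03), with Hsd3b5, a steroid enzyme of male liver, at -1.63 ± 0.13 and Elovl3 at -1.57 ± 0.15. De novo lipogenesis genes were higher in 2 of 18 and lower in 1 (median 0.20, percentile 99.9), with Thrsp at 2.44 ± 0.15, cholesterol biosynthesis genes higher in 1 of 17 (median 0.45, percentile 100), and fatty acid oxidation genes lower in 1 of 27 (median -0.14, percentile 2.43), which was Acot3 at -1.33 ± 0.12. No macrophage gene of 28 (median 0.092) and no lipid droplet gene of 16 (median -0.055) was called.

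Between the chow livers limma called 159 genes, 89 higher and 70 lower (largest adjusted p 0.0476), and none of 26 had another probe called the other way. Without background correction 62 were called, with the authors' values 66, with a 1.5-fold minimum 458, with both tissues normalized and fitted together 300 (normalized together alone, 157), and without the second wild-type chow array 248. Median scaling gave 119 higher and 47 lower, and without the second Fgf1 null chow array the split was 49 higher and 63 lower.

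On HFD, Fgf1 null liver had more lipid droplet, macrophage and neutrophil transcripts and fewer cholesterol synthesis transcripts than wild-type liver. Cidea was at least 35.1-fold higher. Cidec rose by 5.07 ± 0.28 and Gpnmb by 4.51 ± 0.22, and each of these 2 was detected on 1 of 2 wild-type arrays. S100a8, a neutrophil calcium-binding protein, rose by 4.08 ± 0.18, and Fgf21 by 2.47 ± 0.15. Cyp7a1 fell by 1.76 ± 0.12, the acute phase gene Saa2 fell by 3.75 ± 0.16 and Saa1 fell by 2.91 ± 0.28. Scd1 differed by 0.34 ± 0.13 and was not called.

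Lipid droplet genes were higher in 11 of 16 and lower in 0 in Fgf1 null liver on HFD (median 1.23, percentile 100), with Mogat1 at 2.89 ± 0.15, Plin4 at 2.60 ± 0.14 and Pparg at 1.97 ± 0.12 beside Cidea and Cidec. Cholesterol biosynthesis genes were lower in 14 of 17 and higher in 0 (median -1.71, percentile 0), with Sqle at -2.40 ± 0.18, Pmvk at -2.27 ± 0.15, Msmo1 at -2.06 ± 0.13 and Tm7sf2 at -1.96 ± 0.17. Fatty acid oxidation genes were higher in 9 of 27 and lower in 1 (median 0.43, percentile 100), Acot3 at 3.49 ± 0.12 and Acot1 at 2.23 ± 0.26. De novo lipogenesis genes were higher in 1 of 18 and lower in 2 (median -0.29, percentile 0.06), with Acss2 at -1.57 ± 0.13. Xenobiotic metabolism genes were higher in 5 of 21 and lower in 0 (median 0.21, percentile 99.2), with the glutathione transferase Gsta1 at 4.06 ± 0.30, Cyp2b9 at 3.07 ± 0.17 and Cyp3a11 at 2.35 ± 0.13. Mogat1 and Gsta1 were detected on 1 of 2 wild-type arrays.

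Macrophage genes were higher in 15 of 28 and lower in 2 between the HFD livers (median 1.12, percentile 100), with Lyz1 at 2.42 ± 0.12 and Lyz2 at 2.35 ± 0.19, and Cd163 at least 11.8-fold lower. Neutrophil and mast cell genes were higher in 6 of 10 and lower in 0 (median 1.13, and 0.76 at the bound; percentile 100), S100a9 at 3.33 ± 0.15. Cytokine and chemokine genes were higher in 8 of 20 (median 0.71, percentile 100), Ccl4 at least 8.35-fold and Ccl5 at 2.59 ± 0.14, and matrix genes higher in 6 of 27 (median 0.61, percentile 100). Cell cycle genes were higher in 7 of 16 and lower in 1 (median 0.87, and 0.76 at the bound; percentile 100), with the cell cycle inhibitor Cdkn1a at 2.78 ± 0.16 and the replication gene Mcm5 at 1.81 ± 0.19. Acute phase genes were lower in 4 of 21 and higher in 0 (median -0.21, percentile 0.25), Hamp2 at -2.80 ± 0.13. Clock genes were lower in 1 of 15 (median -0.51, percentile 0.01), which was Ciart at -1.33 ± 0.12. Moxd1, at least 24.2-fold lower, and Tff3, a trefoil factor, at least 11.8-fold lower, were the other large falls.

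Between the HFD livers limma called 441 genes, 297 higher and 144 lower (largest adjusted p 0.0486), and none of 78 had another probe called the other way. Without background correction 182 were called, with the authors' values 200 and with a 1.5-fold minimum 1092. Median scaling gave 329 higher and 158 lower.

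The interaction in liver called 703 genes, 403 with a higher and 300 with a lower diet difference in Fgf1 null and none of 140 had another probe called the other way. Cholesterol biosynthesis genes had a lower diet difference in 13 of 17 (median -2.02, percentile 0) and acute phase genes in 8 of 21 (median -0.79, percentile 0). Lipid droplet genes had a higher one in 10 of 16 (median 1.33, percentile 100), fatty acid oxidation genes in 10 of 27 against 1 (median 0.52, percentile 100) and macrophage genes in 14 of 28 against 2 (median 0.97, percentile 100). De novo lipogenesis genes had a lower diet difference in 4 of 18 (median -0.33, percentile 0.17). Without background correction 312 were called, with the authors' values 382 and with a 1.5-fold minimum 1182, and median scaling gave 359 higher and 362 lower. Across genes the diet differences of the 2 genotypes correlated at r = 0.39 (rho 0.35), with 93 genes higher in both against 16.9 expected and 64 lower in both against 5.96, and with 11 higher in wild-type and lower in Fgf1 null against 7.77 and 11 the reverse against 13.0. The genotype differences on chow and on HFD correlated at r = -0.050 (rho -0.055), with 12 genes higher on both against 2.97 and 5 lower on both against 1.13, but also 8 higher on chow and lower on HFD against 1.44 and 12 the reverse against 2.34, so they show no common direction.

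**Figure D4:**
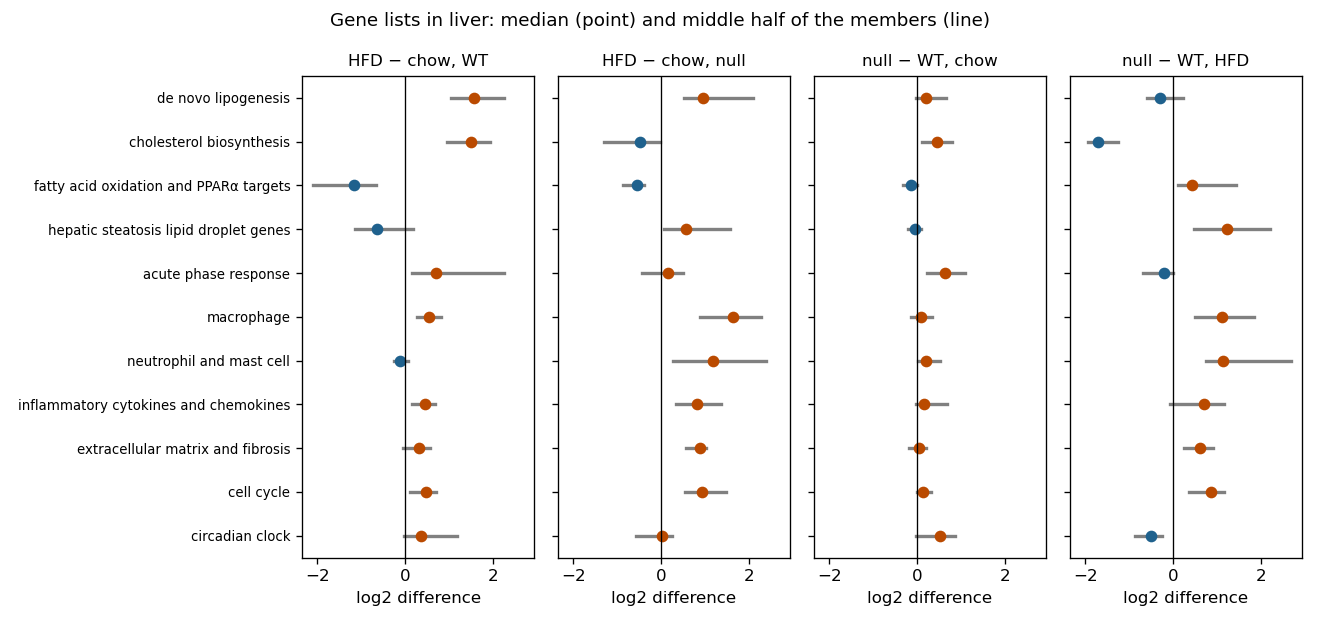
Gene lists in liver, each with the median log2 difference of its members as a point and the central quartiles of the members as a line, for 4 comparisons side by side. Cholesterol biosynthesis lies at 1.49 for diet in wild-type and -1.71 for genotype on HFD, and the lipid droplet list at -0.65 and 1.23.

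With each RNA sample counted once and the genotypes serving as replicates of each diet, limma called 0 genes for diet and 0 for genotype in both tissues. Any diet by genotype interaction counts as error in this additive model. The 0 calls therefore do not show that diet or genotype makes no difference. Unadjusted p values under 0.05 numbered 197 for diet and 73 for genotype among 11935 in eWAT, and 1177 and 302 among 8894 in liver. In liver Serpina7 was first for diet, higher by 5.33 ± 0.30 (adjusted p 0.134), and Camk2b first for genotype (adjusted p 0.161), detected in both null samples and in neither wild-type sample. In eWAT the pancreatic elastase Cela2a came first for diet, at 9.79 ± 0.63 (adjusted p 0.998). In 1 simulated data set per tissue, this fit recovered 84% of 4-fold and 100% of 8-fold changes in liver, with 14 false calls (57 with the gene spreads first tried), but 0% of either in eWAT, where the median standard error was 0.461 against 0.211 in liver. Without the second Fgf1 null chow array 13 genes were called for diet and 1 for genotype in liver.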

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

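Chosen after the result was seen were the tests of exocrine pancreas and liver tissue, of lipase genes apart from other acinar genes, of exchanged diet labels, of dilution, of time of day and of hepatocyte share, and the comparison of Camk2b in eWAT; the test of exchanged genotype labels was set before its value was seen, though after the gene lists. The diet differences of the 2 genotypes differed, by the interaction term against array noise, for 4713 genes in eWAT and 703 in liver. In eWAT the diet difference was larger in samples labelled Fgf1 null for Npy (9.58), Ltf (9.13), Ly6f (8.62), Serpina1f (8.69) and Wfdc13 (8.41), and smaller for Tph2 (-11.05), Serpina1d (-9.84), Serpina1b (-9.77), Saa3 (-8.94) and Cyp2c70 (-8.95). In liver it was larger for Cidec (5.19), Acot3 (4.83), Gpnmb (4.40), Socs2 (3.90) and Cidea (5.66), and smaller for Saa2 (-5.83), Saa1 (-4.60), Hamp2 (-3.89), Moxd1 (-5.06) and Tff3 (-4.61). For Serpina1f, Wfdc13, Cyp2c70, Cidea, Gpnmb, Moxd1 and Tff3 the probe was not above background in at least 1 group, so their values are fitted ones whose size and order are not measured. Npy, Ltf, Ly6f, Tph2 and Cidec were detected on 1 of 2 arrays in 1 group.

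Transcripts of exocrine pancreas were abundant in both HFD eWAT samples, and those of liver in the wild-type HFD sample. Epididymal transcripts were abundant in every eWAT sample except wild-type HFD. Defb42 was at 14.09 and 14.19 in wild-type chow and at 13.02 and 12.84 in chow labelled Fgf1 null. It was at 12.21 and 12.08 in HFD labelled Fgf1 null, against 5.32 and 4.94 in wild-type HFD. Sperm transcripts were abundant in the wild-type chow sample, with Tnp1 at 13.49 and 13.60 against at most 6.73 on the other eWAT arrays. That sample is the baseline of diet in wild-type and of genotype on chow, and enters the interaction. Testis tissue in it, and epididymis tissue in any eWAT sample, were not tested. Lipase genes raised in fat apart from other acinar genes are argued against, since 29 of 32 acinar genes that are not lipases were also called higher in the HFD eWAT sample labelled Fgf1 null than in wild-type HFD. The lipase median minus that of the other acinar genes was -0.020 between these samples, as exocrine pancreas tissue in both HFD eWAT samples would give. More of it would then be in the one labelled Fgf1 null. Ins2 was at 7.81 there and near background elsewhere, but it is 1 of 4 measured endocrine pancreas genes. Their median for genotype on HFD was 0.40, and 0.0062 with undetected genes at their bound, so that list adds no support. Of the 100 most abundant liver-enriched genes, 87 were at least 4-fold higher in wild-type HFD eWAT than in the HFD sample labelled Fgf1 null. Their levels in wild-type HFD eWAT correlated across genes at 0.90 with wild-type HFD liver and at 0.91 with Fgf1 null HFD liver. The other eWAT samples correlated at 0.33 to 0.49 with wild-type HFD liver. Liver tissue or RNA in wild-type HFD eWAT is thus a candidate source, and the correlation does not single out the liver of 1 group. Cyp4a14, however, was higher in wild-type HFD eWAT (10.23) than in wild-type HFD liver (7.22, normalized apart). Whether diet or genotype acts on these genes within fat stays open and untested, with 1 RNA sample per group.

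Macrophage and matrix genes, and Lep among the fat cell genes, had opposite diet differences in the 2 genotypes of eWAT. Dilution of fat RNA by other organs in the HFD sample labelled Fgf1 null is argued against as the only source. The adipocyte median lay 1.83 above the macrophage median for that diet difference, where dilution alone would lower both alike. Dilution beside a change of macrophage genes is not excluded. Dilution in the wild-type chow sample, where sperm transcripts were abundant, was not tested. Relative to wild-type chow, adipocyte medians were 1.41 in wild-type HFD and 1.23 in the chow sample labelled Fgf1 null. Macrophage medians were 1.77 and 2.61. Both lists were higher in both samples, the direction that dilution of wild-type chow would give, so such dilution stays open. In the chow sample labelled Fgf1 null the macrophage median lay above the adipocyte median, where dilution alone would raise both alike. Smooth muscle medians went the other way, at -1.43 and -0.61. An exchange of the diet labels of the samples labelled Fgf1 null cannot be told apart from a genotype effect. Over all genes the diet differences correlated at 0.10, between bounds of -0.3 and 0.3 that were chosen after the result was seen. Exocrine pancreas genes, higher on HFD in both genotypes, enter this correlation, so it cannot decide the question for fat. An exchange of the genotype labels of the chow samples is open too. The genes tested were called the same way between genotypes on both diets in liver. Of the 6 that changed in chow eWAT 3 went the same way there, beside 6 of 8 on HFD. Cyp7a1, a hepatocyte gene, is among the 6 on HFD, and liver tissue in wild-type HFD eWAT would give it that direction. The count cannot decide, since the liver genotype differences showed no common direction. Between the diets 12 and 5 genes were called alike in liver and 8 and 12 opposite ways. Camk2b, 1 of the 3, was higher by 3.28 ± 0.21 in the chow sample labelled Fgf1 null, as its label would have it, while Fgf1 at 0.67 ± 0.17 above wild-type was not lower. The genotype itself, and differences between single mice, remain among the open explanations.

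Lipid droplet, macrophage and cholesterol synthesis genes differed between the genotypes in liver on HFD. A lower share of hepatocytes in the Fgf1 null sample is argued against as the only source. The cholesterol biosynthesis median lay below that of fatty acid oxidation by -2.14, both being pathways of hepatocytes. A lower share beside changed pathways is not excluded, since macrophage and neutrophil genes were higher. The hepatocyte list was read in eWAT only. Clock genes with the phase of Dbp minus those with the phase of Arntl differed by -1.09 between these livers (8 and 3 genes), which is consistent with a different time of day at collection; the same difference was 1.35 for genotype on chow and 1.91 for diet in wild-type. Nr1d1, counted with the phase of Dbp, was lower in Fgf1 null on chow, against that phase's median of 0.60. Cholesterol synthesis and lipid droplet genes may follow the hour and feeding state, and an effect of genotype was not separated from this. The same limit holds for diet in wild-type liver and for the liver interaction. For diet in Fgf1 null liver the clock difference was 0.057.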

How the results depend on the processing

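The alternatives were set before the data were seen, except those without genes or members that follow other organs. Of 263 counts under an alternative, 228 were within 1.5 times the reported count and 35 were not. Of 6555 values for 345 gene results, 6476 kept direction and side of the threshold, 62 lost the call, 14 gained it and 3 reversed. Of 2295 list medians, 1516 moved by less than the array spread, 777 moved by more and 2 reversed. The medians include those without liver-enriched members, also for comparisons in which these are not read.

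Counts are given in the order diet in wild-type, diet in Fgf1 null, genotype on chow, genotype on HFD and interaction. Quantile normalization without background correction, which shrinks differences of dim genes by construction, gave 2305, 583, 1834, 695 and 2947 in eWAT and 227, 310, 62, 182 and 312 in liver. The authors' normalized values gave 2338, 576, 1850, 695 and 2987 in eWAT and 238, 369, 66, 200 and 382 in liver; the cause was not tested. A 1.5-fold minimum, which admits smaller changes, gave 6131, 2863, 5449 and 2818 in eWAT (the interaction stayed within 1.5 times) and 1389, 1773, 458, 1092 and 1182 in liver. For liver genotype on chow, both tissues in the same fit gave 300, with normalization and the genes tested changed too, and normalization over all arrays alone gave 157; which of the other changes moved it was not tested.

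Leaving out each array in turn gave ranges, in the same order, of 3941 to 4025, 1168 to 1404, 3191 to 3389, 1332 to 1430 and 4613 to 4786 in eWAT and 487 to 599, 708 to 783, 112 to 248, 394 to 445 and 525 to 839 in liver, with the lone array assumed to vary like the other groups. The highest count for genotype on chow in liver, 248, came without the second wild-type chow array. With RNA samples as replicates the range was 0 to 13 for diet and 0 to 1 for genotype in liver and 0 to 0 for both in eWAT; 13 and 1 came without the second Fgf1 null chow array, and 1 for diet came from replicate 1 arrays alone and without the second wild-type chow array.

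Pparg for genotype on HFD in eWAT, not called, reversed to 0.032 with the mean of its probes and to 0.020 without the second wild-type HFD array (range -0.13 to 0.020 over arrays left out), all near 0. Mmp13 for diet in eWAT labelled Fgf1 null reversed to 0.079 without the first chow array (range -2.53 to 0.079); the cause was not tested. Median scaling reversed the liver diet medians in wild-type of the bile acid list (0.022) and the gluconeogenesis list (0.021), with the median of all genes moved to 0.26. Median scaling also carried Adipoq past 2-fold in eWAT, at 1.08 for diet in wild-type and 1.01 for genotype on chow, where it moved the medians of all genes to 0.30 and 0.27. The replicate number as a block left 3969, 1213, 3260, 1343 and 4702 in eWAT and 505, 762, 151, 438 and 655 in liver; the differences between arrays 2 and 1 of the groups correlated between -0.068 and 0.051, so the numbers pair nothing. A slide block was not run, since the files give no slide. Signal near background limits the dim genes: a fold against an undetected group is a bound.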

Other observations

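The restriction of list medians to members not enriched in liver was chosen after the results were seen, and no further test was run for this part. Lymphocyte transcripts in eWAT differed in the same directions as macrophage genes. Of 13 B and plasma cell genes 7 were higher on HFD in wild-type (median 1.19, percentile 99.9) and 7 lower on HFD in samples labelled Fgf1 null (median -1.18, percentile 0), and 7 were higher on chow in the sample labelled Fgf1 null (median 1.27); Cd79b, part of the B cell receptor, rose by 1.97 ± 0.17 in wild-type. Of 15 T and NK cell genes 5 were higher (median 0.67), 6 lower (median -0.87, and -0.68 with undetected genes at their bound) and 7 higher (median 0.89) in the same 3 comparisons, with the interleukin receptor gene Il7r at 2.26 ± 0.16, -3.10 ± 0.16 and 4.46 ± 0.16. On HFD 4 B cell and 4 T and NK cell genes were lower in the sample labelled Fgf1 null, with 0 higher in both lists. Of 13 neutrophil and mast cell genes 7 were higher and 2 lower in chow eWAT labelled Fgf1 null (median 1.02). Among the higher were the mast cell genes Cpa3 at 2.94 ± 0.15 and Mcpt4 at 2.88 ± 0.17 and the neutrophil gene S100a8 at 3.30 ± 0.13. Interferon response genes were higher in 8 of 16 on HFD in wild-type (median 0.95) and in 10 of 16 between the chow samples (median 1.16), Gbp3 at 2.40 ± 0.17 there.

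Endothelial genes were higher on HFD in 13 of 22 and lower in 0 in wild-type eWAT (median 1.04, percentile 100), and in samples labelled Fgf1 null 2 were higher and 1 lower (median 0.50, percentile 100). Nos3, the nitric oxide synthase of endothelium, rose by 2.48 ± 0.11 in wild-type, and Vegfa, the vascular growth factor, by 2.17 ± 0.17 in samples labelled Fgf1 null. Cell cycle genes were lower on HFD in 7 of 22 in each genotype, with 2 higher in wild-type and 0 in samples labelled Fgf1 null (medians -0.36 and -0.76, the latter -0.65 at the bound), Cdc20 at -2.90 ± 0.13 in wild-type and Top2a at -2.41 ± 0.27 in the other, where 1 of 2 HFD arrays detected it. Sperm transcripts were abundant in the wild-type chow sample, and whether testis RNA there adds to the wild-type fall was not tested. Smooth muscle genes were lower in 8 of 13 and higher in 3 in wild-type eWAT on HFD (median -1.43, percentile 0.01), with Actg2 at -4.95 ± 0.15 and Myh11 at -3.58 ± 0.13, beside the fall of epididymal genes, whose ducts hold smooth muscle. Brown and beige fat genes were lower in 4 of 9 and higher in 0 on HFD in samples labelled Fgf1 null (median -0.86, percentile 0.02), and Cox8b was higher by 3.55 ± 0.17 between the chow samples. Erythrocyte genes were higher in 4 of 6 and lower in 1 in wild-type eWAT on HFD (median 1.63), Slc4a1 at 3.02 ± 0.13, and likewise higher in 4 of 6 and lower in 1 in the chow sample labelled Fgf1 null than in wild-type (median 1.53), Hbb-bt at 2.26 ± 0.14. In liver, 0 of 35 oxidative phosphorylation genes were called in any of the 4 simple comparisons, with medians from -0.14 to 0.023. The exocrine pancreas genes other than lipases had liver medians of 0.86 (0.69 at the bound) for diet in wild-type and 0.21 (0.10 at the bound) in Fgf1 null. For genotype they were -0.14 on chow and -0.50 on HFD, and their source in liver was not tested. Sex-linked genes differed in none of the comparisons, 0 of 4 measured in eWAT and 0 of 3 in liver.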
